A study of Danio rerio with 28 samples.

How the data were processed

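Gene expression was measured in whole zebrafish larvae (Danio rerio) with 28 one-colour Agilent arrays, 1 array per RNA sample. The samples fell into 8 groups, set by the form of the insensitive munition IMX-101, parent or UV-treated, and by 4 concentrations, from 0 mg/L through 3.8 mg/L and 30.2 mg/L up to 58.2 mg/L. Each 0 mg/L group held 2 samples and each of the other 6 groups held 4. Group, concentration and replicate number were taken from the sample labels. The series design text gives 85.2 mg/L where the sample labels give 58.2 mg/L, and 58.2 mg/L was used throughout. The labels do not say whether the 0 mg/L samples of the UV-treated set held UV-irradiated water.

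RNA was extracted from 4 whole fish per replicate and 600 ng of it were amplified and labelled with Cy3, per the labels' protocols, which also ask for an RNA integrity number above 7.0. Slides were quantified with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited scanner values are linear spot intensity values. The processed intensity had been background-subtracted and detrended within each array by that program and had not been scaled between arrays, per the file headers. Probe coordinates in the deposited files are those of design 036575 on the Zv9 build (danRer7). The deposited files also carry 0 or 1 flags per spot for a signal well above background, saturation and outliers. The authors also deposited a table of processed values for the same arrays, on a log2 scale. Its scale and centring are not given in the sources used here and were found by setting each of its columns against the scanner values: 43603 of its 43659 rows matched an array probe and the correlation per array lay between 0.999988 and 0.999998 after log2 transformation, subtraction of the 75th percentile of the array and subtraction of the median of each probe over the 28 arrays. With this match none of scale, centring and direction stayed unknown.

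The medians of the 28 columns of that table ranged from -0.32 to 0.22. They were -0.32 and 0.16 for the parent 0 mg/L samples, and 0.03, -0.04, -0.14 and 0.14 for parent 3.8 mg/L. They were -0.11, 0.21, -0.16 and -0.21 for parent 30.2 mg/L and 0.03, 0.08, 0.09 and 0.19 for parent 58.2 mg/L. For the UV-treated samples the medians were 0.0020 and 0.05 at 0 mg/L and 0.00085, 0.07, -0.0070 and -0.04 at 3.8 mg/L. They were 0.02, -0.0099, 0.22 and -0.01 at 30.2 mg/L and -0.19, -0.0061, -0.06 and 0.0086 at 58.2 mg/L.

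From the scanner files, the log2 of the processed signal minus the 75th percentile of the array was computed for 61657 non-control spots per array. Spots with an outlier flag were left out, 13 to 408 per array, and 0 spots were saturated. Spots of 1 probe were averaged, which gave 43603 probes. Probes well above background on at least 4 of the 28 arrays were tested, 37319 in all, and 37314 in comparisons with the 0 mg/L samples of the UV-treated set, because 5 probes had no value there. The share of spots well above background ranged from 63.4% to 81.5% per array (median 76.1%), and the 75th percentile of the processed signal from 424 to 2519 (median 1534). The number of arrays limits the precision. P-values measure the spread between these samples, each a pool of 4 fish from an exposure replicate.

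Gene names were updated through a RefSeq gene table without transcript versions: 25724 of 43603 probes were named by accession, 4313 by a current symbol and 1146 by a synonym, and 12420 kept the name in the array file. For counts by gene, the probe with the highest mean over all arrays stood for the gene, which gave 22178 entries, 13534 of them with a gene symbol. Where probes of 1 gene differ, this rule decides which value is printed. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least N-fold", from the mean of the brighter group over the mean of the dim one, where each dim array takes the higher of its lowest signal among probes well above background and the signal of the probe itself.

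Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single model with 8 group means, so that all arrays shared the estimate of the spread. P-values were adjusted by the method of Benjamini and Hochberg over all tested probes, and 0.05 was the threshold. Errors of log2 changes are the model's SE, two-sided throughout. The comparisons were each concentration against the 0 mg/L samples of its own set, UV-treated against parent material at each concentration, the interaction of form and concentration, and 58.2 against 3.8 mg/L within each form. The average of the difference between forms over the 3 concentrations was added after the data were seen, as was the comparison of the 0 mg/L samples of both sets.

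The comparisons, the alternatives, 38 lists of genes for pathways and cell types, and the rule for naming genes were fixed before the data were examined. The lists were tested with camera against all other genes at a preset correlation of 0.01, and again with an estimated correlation, with fry beside them. Their counts are given over all probes tested and adjusted over the list alone. Another 7 lists were chosen after the data were seen and carry counts and medians without a list test. Named genes were the 8 largest rises and 8 largest falls past 0.05 of each comparison, up to 4 members past 0.05 from each list, and 19 genes given at 58.2 mg/L whether they passed or not. With fewer than 3 genes past 0.05, the 4 higher and 4 lower genes of smallest p were taken. Clone, contig and accession names were left out. Of the 19, gstp1, txnrd1 and hbae1 are listed under their current symbols gstp1.2, txnrd3 and hbae1.1, and no probe was matched to cdkn1a, which was not analysed here. Genes named outside this rule are said to have been chosen after their values were seen.

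Slide was taken from the names of the scanner files, and the 28 arrays lay on 4 slides. Slide was tested as a block, and changes were also computed within slides that held both groups. Other alternatives were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, no filter on dim probes, a filter for all arrays, 1 probe per gene, trend and robust variance, the replicate number as a block, all 4 samples at 0 mg/L as 1 group, the deposited table and each array left out in turn. A mean of 33 oocyte genes as a covariate, with and without slide, and a fit without the 2 dimmest arrays were added after the data were seen.

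The steps were tested on simulated data with the real group sizes and spread, over 36834 probes with 50 changed at each size. At log2 changes of 1, 2 and 3 the share recovered was 14%, 60% and 88% for parent 58.2 mg/L against 0 mg/L, and 16%, 58% and 94% for UV-treated 58.2 mg/L against 0 mg/L. It was 32%, 72% and 98% between the forms at 58.2 mg/L, 22%, 72% and 94% for parent 58.2 against 3.8 mg/L, and 28%, 78% and 96% for UV-treated 58.2 against 3.8 mg/L. Unchanged probes were called at a rate of at most 0.0218%, and camera called 0 of 40 random lists. Probes were simulated independently of each other, without correlation between genes or differences shared by samples. These rates therefore do not show how often false calls arise in the real data.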

Results

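Zebrafish larvae were exposed for 96 h without water renewal to IMX-101, a munition formulation that holds 2,4-dinitroanisole, nitrotriazolone and nitroguanidine, either as the parent material or after 4 h of UV light in a photo-reactor. The question was how gene expression in whole larvae changes with concentration and whether UV treatment alters that response. Each beaker held 10 larvae and each RNA sample came from 4 whole fish. There were 2 samples at 0 mg/L for each form and 4 at each of the other concentrations, of which 58.2 mg/L was the highest, 3.8 mg/L the lowest and 30.2 mg/L between them. Array pairs correlated between 0.850 and 0.979 over all tested probes, and the lowest correlation within a group was 0.886. The first principal component held 32.7% of the variance and the next held 14.5%. Between the 0 mg/L samples of both sets 1 probe differed, higher in the UV-treated set and named si:dkey-56d12.4 (log2 3.68 ± 0.54 SE, n = 2 against 2, adjusted p = 0.0171 by limma), chosen after its value was seen. Both UV-treated 0 mg/L samples lay on slide 2 and the parent ones on slides 1 and 3. Set and slide therefore cannot be told apart in that comparison. All log2 changes below carry the SE of the limma model.

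At 3.8 mg/L few genes differed from the 0 mg/L samples. In parent material 4 probes were higher and 0 lower, with 3102 probes at an unadjusted p under 0.05. They measured irak4, a kinase of Toll-like receptor signalling (log2 1.42 ± 0.20, n = 4 against 2, adjusted p = 0.00819), the cadherin cdh7a (at least 2.73-fold, adjusted p = 0.0431), the anion exchanger slc4a2a (1.46 ± 0.25, adjusted p = 0.0431) and si:dkey-56d12.4 (2.86 ± 0.46, adjusted p = 0.0431). The last and slc4a2a, whose brightest probe did not pass, were chosen after their values were seen. The probe of si:dkey-56d12.4 is also the one that differed between the 0 mg/L samples of both sets. Its rise here may thus come from the parent 0 mg/L samples. With slide as a block limma called 0 probes in this comparison. The call of irak4 ended without parent 0 mg/L replicate 1 (1.36, adjusted p = 0.0997). That of cdh7a ended in 5 of the 6 fits that left out 1 array, all but the one without parent 0 mg/L replicate 2. The count was 1 without parent 3.8 mg/L replicate 2 or 4, 2 without replicate 1 or 3, and 123 without parent 0 mg/L replicate 2. In UV-treated material limma called 0 probes at 3.8 mg/L, with 2498 at an unadjusted p under 0.05 and a smallest adjusted p of 0.414. The genes of smallest p did not pass and included the cone opsins opn1mw4 (4.32 ± 0.93) and opn1lw1 (2.39 ± 0.47) on the higher side and the T-box gene tbx16 (-1.69 ± 0.36) on the lower side. Without 1 of the UV-treated 0 mg/L samples the count was 15 (replicate 1 left out) or 169 (replicate 2 left out). No gene list was below 0.05 with an estimated correlation at 3.8 mg/L in either form. The cell cycle list had a median of -1.18 in parent material (adjusted p = 0.918 with an estimated correlation) and 0 of its 52 measured members passed.

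At 30.2 mg/L of parent material, heat shock genes and haem oxygenase rose. The inducible chaperone gene hsp70 rose by log2 4.43 ± 0.48 (n = 4 against 2, adjusted p = 9.76e-05), hsp70l by 4.08 ± 0.53 (adjusted p = 0.000349) and hsp70.3 by 4.00 ± 0.45 (adjusted p = 9.76e-05). The haem-degrading enzyme gene hmox1a rose by 4.42 ± 0.72 (adjusted p = 0.00634), and the stretch-responsive gene ankrd1b by 3.78 ± 0.60 (adjusted p = 0.00552). The aryl hydrocarbon receptor target cyp1a rose by 2.36 ± 0.43 (adjusted p = 0.0125) and star, which carries cholesterol into mitochondria for steroid synthesis, by 2.60 ± 0.53. The largest falls included nr0b2a, a repressor of bile acid synthesis (-3.43 ± 0.64, adjusted p = 0.015), the transglutaminase gene tgm5l (-2.79 ± 0.53), and dao.3 (-2.85 ± 0.56), for an oxidase of D-amino acids. The liver genes fabp10a (-2.36 ± 0.51, a fatty acid binding protein) and gc (-1.94 ± 0.43, the vitamin D binding protein) also fell. Of 53 liver genes 0 rose and 3 fell (1 and 7 when adjusted over the list alone, adjusted p = 0.69 with an estimated correlation). Without parent 0 mg/L replicate 1 the calls of ankrd1b (3.39, adjusted p = 0.0824), cyp1a (2.05, adjusted p = 0.128), star (2.33, adjusted p = 0.158) and nr0b2a (-3.11, adjusted p = 0.127) ended, and the last pair also lost theirs without parent 30.2 mg/L replicate 1 (adjusted p = 0.0662 and 0.0584). The calls of tgm5l and dao.3 ended without parent 0 mg/L replicate 2 (-2.07 and -2.21) or parent 30.2 mg/L replicate 4 (-2.59 and -2.61), and that of dao.3 also without parent 30.2 mg/L replicate 1 (-2.73).

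Of 35 measured heat shock and chaperone genes, 7 rose, 0 fell and 28 did not pass at 30.2 mg/L of parent material. There were 13 rises when adjusted over the list alone, and the list median was 0.54 (adjusted p = 0.0083 with an estimated correlation). It was 0.46 with slide as a block and 0.64 within the slide that held both groups. Of 26 sterol synthesis genes 3 rose and 0 fell, with sqlea (2.62 ± 0.57, squalene epoxidase), msmo1 (2.07 ± 0.46) and acat2 (1.23 ± 0.27). Adjusted over the list alone 10 rose, the median was 0.85, and the list's call was lost (adjusted p = 0.195 with an estimated correlation). Of 46 proteasome and muscle wasting genes 1 rose, psmd4a (1.23 ± 0.27), and 20 rose when adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). Of 78 ribosomal protein genes 0 passed, and 38 were lower when adjusted over the list alone, with a median of -0.73 (adjusted p = 0.414 with an estimated correlation). In all, 147 probes were higher and 79 lower by limma. A fit with slide as a block called 60 probes (46 higher and 14 lower), that with the oocyte score 504 (278 and 226) and that without the 2 dimmest arrays 415 (237 and 178). Without parent 30.2 mg/L replicate 1, 2 or 4 the count was 52, 104 or 68, and without parent 0 mg/L replicate 1 it was 52. The heat shock genes named here and hmox1a were called in all 6 fits that left out 1 array. Without parent 0 mg/L replicate 1 the calls of sqlea (2.17, adjusted p = 0.2), msmo1 (1.53, adjusted p = 0.242), acat2 (1.24, adjusted p = 0.147), psmd4a (0.92, adjusted p = 0.228), fabp10a (-2.55, adjusted p = 0.126) and gc (-2.05, adjusted p = 0.14) ended. They also ended without parent 30.2 mg/L replicate 1 or 4, all but that of msmo1 without replicate 2, and those of acat2, fabp10a and gc without parent 0 mg/L replicate 2.

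At 58.2 mg/L of parent material the genes that rose included haem oxygenase, chaperone, glutathione transferase and adult globin genes, and the difference from 30.2 mg/L was not tested. The gene hmox1a rose by log2 6.2 ± 0.72 (n = 4 against 2, adjusted p = 1.6e-05), with its probe on chromosome 3 from 27021597 to 27023156 in Zv9. Other large rises were those of ankrd1b (5.87 ± 0.60), the chaperone genes hspa1b (5.75 ± 0.71) and hsp70 (5.42 ± 0.48, adjusted p = 7.24e-07), and the glutathione transferase gene gsta.2 (5.02 ± 0.85). Heat shock gene hsp70l rose by 4.77 ± 0.53, measured on chromosome 8 from 5009181 to 5009240. The adult globin genes hbba2 (5.22 ± 1.08, adjusted p = 0.00315, chromosome 3, 55943243 to 55943302) and hbaa2 (4.86 ± 1.11, adjusted p = 0.00624, chromosome 3, 55945847 to 55945906) rose, and both lost their calls without parent 0 mg/L replicate 1 (4.95, adjusted p = 0.0758, and 4.97, adjusted p = 0.0825). The cytochrome P450 gene cyp2k6 was at least 16.6-fold higher (adjusted p = 7.18e-05, chromosome 3, 12443101 to 12443160) and the leptin gene lepb at least 12.4-fold (adjusted p = 0.000303). In the fit with slide as a block hmox1a was at 6.43 and hbba2 at 5.57, and within the slide that held 1 array of each group they were at 6.4 and 5.79.

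Among genes that fell at 58.2 mg/L of parent material, the skin keratin gene krt1-19e changed by -6.35 ± 0.67 (adjusted p = 6.07e-06, chromosome 19, 5963639 to 5963698), and by -6.62 with slide as a block. The lipogenic gene thrsp changed by -8.04 ± 1.79 (adjusted p = 0.00528), nos2a, an inducible nitric oxide synthase, by -4.11 ± 0.90 (adjusted p = 0.00456, chromosome 5, 45415028 to 45415161), the chitinase gene chia.3 by -4.29 ± 0.80 and the green cone opsin opn1mw1 by -3.83 ± 0.64. The signal of nos2a was not well above background in parent 58.2 mg/L replicates 2 and 4, so the size of its fall is uncertain. The liver genes nr0b2a (-4.14 ± 0.64), ahsg2 (-3.43 ± 0.53) and gc (-2.60 ± 0.43) also fell. Of 53 liver genes 5 rose and 7 fell (6 and 8 when adjusted over the list alone), with a median of -0.08 (adjusted p = 0.828 with an estimated correlation) that was 0.03 with slide as a block. Of the 8 largest falls, bmp15 (-6.13 ± 1.72), foxh1 (-5.55 ± 1.57) and zp3d.2 (-5.31 ± 1.66) are known for expression in oocytes. The others were mhc2dga (-7.13 ± 2.04), of antigen presentation, the enamel gene enam (-6.27 ± 1.96) and cyp11a1.1 (-5.29 ± 1.62), for a steroid synthesis enzyme. Without parent 0 mg/L replicate 1 the calls of all these 6 ended, with bmp15 at -4.78 (adjusted p = 0.327), foxh1 at -4.12 (adjusted p = 0.364), zp3d.2 at -4.11 (adjusted p = 0.411), mhc2dga at -7.49 (adjusted p = 0.171), enam at -6.71 (adjusted p = 0.205) and cyp11a1.1 at -4.35 (adjusted p = 0.359). They ended too without parent 58.2 mg/L replicate 3, where their adjusted p lay between 0.0568 (bmp15) and 0.0987 (zp3d.2), and that of thrsp ended without parent 0 mg/L replicate 1 (-8.44, adjusted p = 0.0668). When slide was a block zp3d.2, mhc2dga and enam lost their calls (adjusted p = 0.0748, 0.0706 and 0.113). A mean of 33 oocyte genes, a score chosen after the data were seen, stood at -0.11 (SD 1.69, n = 4) in these samples and at 3.76 (SD 1.18, n = 2) at 0 mg/L, in log2 units.

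The heat shock list had 14 members that rose, 0 that fell and 21 that did not pass at 58.2 mg/L of parent material (17 rose and 1 fell when adjusted over the list alone). Its median was 0.86 (adjusted p = 0.0112 with an estimated correlation), 0.90 with slide as a block. Of 46 proteasome and muscle wasting genes 36 rose and 0 fell, among them psmc1b (2.19 ± 0.35), psmb3 (2.13 ± 0.31) and psmd4a (1.94 ± 0.27), which encode parts of the proteasome. Adjusted over the list alone 41 rose and 1 fell, and the list's call was lost (adjusted p = 0.22 with an estimated correlation). Of 42 antioxidant genes 15 rose and 3 fell, with hmox1a, the thioredoxin gene txnb (2.79 ± 0.46) and glutathione reductase gsr (2.29 ± 0.30) on the higher side (22 rose and 3 fell when adjusted over the list alone, adjusted p = 0.434 with an estimated correlation). Of 33 erythroid genes 10 rose and 0 fell, including the anion exchanger slc4a1a (3.35 ± 0.43, chromosome 3, 19955787 to 19955986) and the haem synthesis gene alas2 (2.16 ± 0.39, chromosome 8, 21906939 to 21906998). Adjusted over the list alone 13 rose, with a median of 0.88 (adjusted p = 0.305 with an estimated correlation). Of 31 macrophage and neutrophil genes 8 rose and 0 fell, with mpx (3.50 ± 0.82, myeloperoxidase) and lect2l (3.44 ± 0.83), and 8 rose and 1 fell when adjusted over the list alone (adjusted p = 0.736 with an estimated correlation). The calls of alas2 (1.46, adjusted p = 0.0981), mpx (3.07, adjusted p = 0.157) and lect2l (3.30, adjusted p = 0.131) ended without parent 0 mg/L replicate 1. Of 52 cell cycle genes 0 rose and 20 fell, with ccnb1 (-4.33 ± 1.44), ccna2 (-4.04 ± 1.23) and aurka (-3.83 ± 1.26). Their calls ended without parent 0 mg/L replicate 1 (-3.48, -2.95 and -2.64, adjusted p = 0.431, 0.429 and 0.509) and without parent 58.2 mg/L replicate 1, 3 or 4 (adjusted p from 0.0586 for ccna2 to 0.125 for ccnb1). Among them 43 fell when adjusted over the list alone, the list median was -2.05 (adjusted p = 0.495 with an estimated correlation), and the oocyte score of these samples is the one given above. Of 31 hypoxia genes 7 rose and 0 fell, with lepb among them, and 8 rose when adjusted over the list alone (adjusted p = 0.729 with an estimated correlation). The 78 ribosomal protein genes had a median of -0.47 and 0 passed (adjusted p = 0.736 with an estimated correlation), and their direction flipped under quantile normalization (0.08).

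Of the genes given whether they passed or not, 18 were measured. The antioxidant genes prdx1 (1.78 ± 0.38, adjusted p = 0.00389), gclc (1.00 ± 0.28, adjusted p = 0.0207) and srxn1 (0.98 ± 0.30, adjusted p = 0.0354) rose at 58.2 mg/L of parent material, as did cyp1a (2.47 ± 0.43, adjusted p = 0.000756, chromosome 18, 4985480 to 4985539), hmox1a and hsp70l. The metallothionein gene mt2 fell (-1.71 ± 0.52, adjusted p = 0.0344), as did catalase cat (-1.12 ± 0.34, adjusted p = 0.0319) and superoxide dismutase sod1 (-0.88 ± 0.27, adjusted p = 0.0347). Without parent 0 mg/L replicate 1 the calls of mt2 (-0.59), srxn1 (0.58), cat (-1.02), sod1 (-0.93) and gclc (1.13) ended. Without replicate 2 those of gclc (0.87), prdx1 (0.98), cat (-1.22) and sod1 (-0.82) ended. Leaving out parent 58.2 mg/L replicate 1 or 3 also ended those of mt2, srxn1, cat and sod1. Leaving out parent 58.2 mg/L replicate 2 ended those of cat and sod1 too, and replicate 4 that of mt2. The other 9 did not pass: nqo1 was at 1.29, gclm at 0.83, txnrd3 at 0.78, pck1 at 0.64, hbae1.1 at 0.61, fkbp5 at 0.44, mdm2 at 0.39, gstp1.2 at 0.05 and vtg1 at -0.15. In all, limma called 3260 probes higher and 1412 lower, and the median shift of all tested probes was 0.16. With slide as a block 3048 probes were called (2444 higher and 604 lower), 2913 of them shared with the 4672. All 4 samples at 0 mg/L as 1 group gave 7838 (4864 and 2974). With the oocyte score as a covariate 1730 of the 4672 stayed called. The count was 742 without parent 0 mg/L replicate 1, 7866 without parent 0 mg/L replicate 2 and 2957 without parent 58.2 mg/L replicate 1, and 2390 (1264 higher and 1126 lower) with the oocyte score as a covariate.

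**Figure D1:**
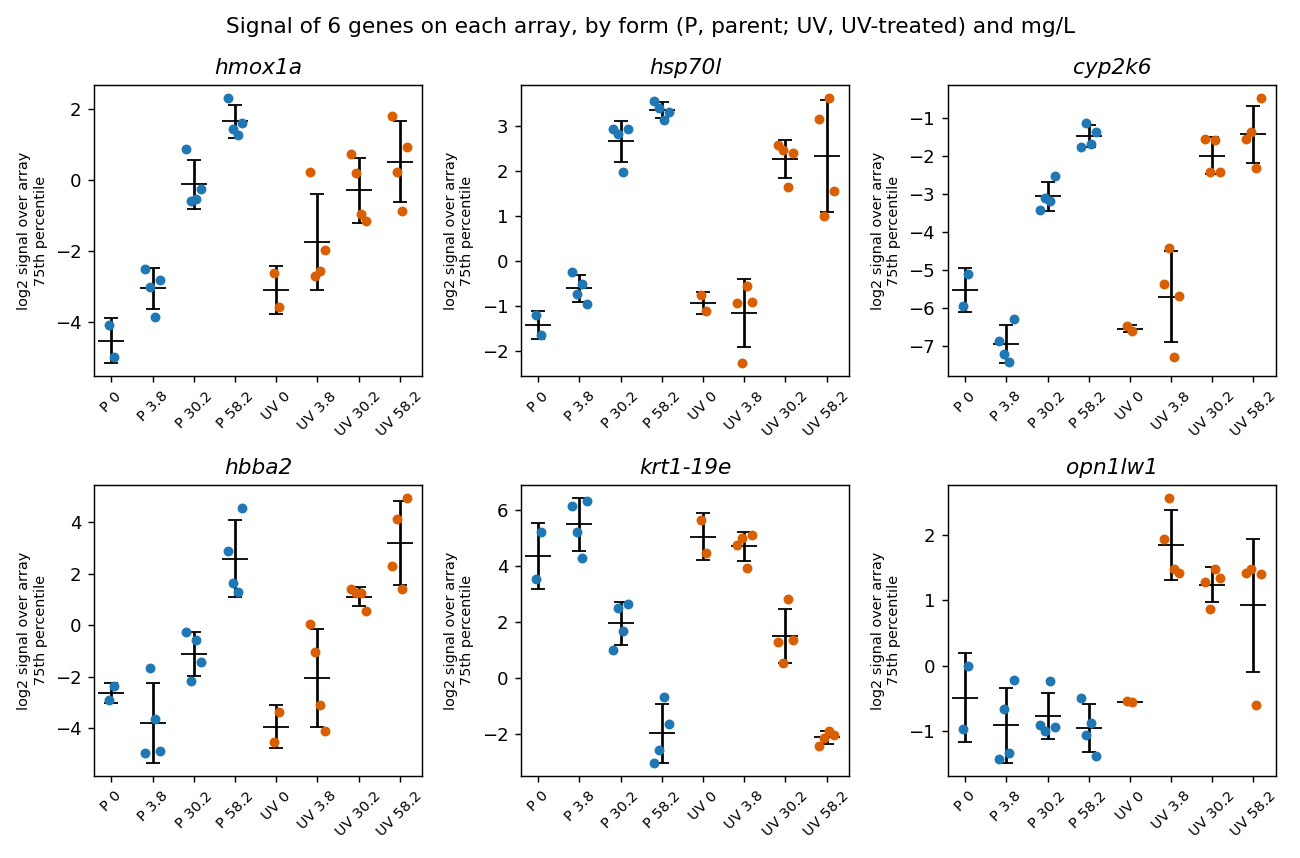
Log2 signal over the 75th percentile of the array (vertical axis) for hmox1a, hsp70l, cyp2k6, hbba2, krt1-19e and opn1lw1, 1 point per array, by group (horizontal axis, P for parent and UV for UV-treated material, mg/L), with the mean and SD of each group. Between 0 and 58.2 mg/L hmox1a differed by log2 6.2 in parent and 3.63 in UV-treated material, and krt1-19e by -6.35 and -7.17.

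At 30.2 mg/L of UV-treated material, heat shock, sterol synthesis and erythroid genes rose. Heat shock gene hsp70 rose by log2 4.80 ± 0.48 (n = 4 against 2, adjusted p = 2.31e-05), hsp70.3 by 3.86 ± 0.45 and hsp70l by 3.2 ± 0.53. The gene cyp2k6 was at least 15.7-fold higher (adjusted p = 0.000147). Of 26 sterol synthesis genes 9 rose and 0 fell, with lss (3.30 ± 0.54, lanosterol synthase), sqlea (3.18 ± 0.57) and hmgcra (3.03 ± 0.51), the rate-limiting reductase of the pathway. When adjusted over the list alone 15 rose, and the median was 1.25 (adjusted p = 0.044 with an estimated correlation), 1.13 with slide as a block and 0.97 within the shared slide. Of 35 heat shock genes 6 rose and 0 fell, 13 rose when adjusted over the list alone, and the median was 0.55 (adjusted p = 0.044 with an estimated correlation). Of 33 erythroid genes 6 rose and 0 fell, with hbba2 (5.06 ± 1.08, adjusted p = 0.0264), slc4a1a (3.35 ± 0.43), alas2 (2.26 ± 0.39) and the erythroid transcription factor klf1 (2.17 ± 0.47). With 11 rises when adjusted over the list alone, the list median was 0.73 (adjusted p = 0.0475 with an estimated correlation), 0.80 with slide as a block. The falls included krt1-19e (-3.55 ± 0.67, adjusted p = 0.0115) and itln2, an intelectin, at least 16.7-fold lower (adjusted p = 0.0234). The gene hmox1a, at 2.82 and chosen after its value was seen, did not pass (adjusted p = 0.0669). The call of hbba2 was lost with slide as a block (5.35, adjusted p = 0.0868). Without UV-treated 0 mg/L replicate 1 the calls of hbba2 (4.48, adjusted p = 0.296), klf1 (1.38, adjusted p = 0.487), alas2 (2.06, adjusted p = 0.124), lss (2.37, adjusted p = 0.171), sqlea (2.71, adjusted p = 0.171), hmgcra (2.58, adjusted p = 0.14), krt1-19e (-2.96, adjusted p = 0.23) and itln2 (adjusted p = 0.237) ended. The calls of hbba2 and klf1 also ended without UV-treated 30.2 mg/L replicate 1, 2 or 3, and that of itln2 without UV-treated 30.2 mg/L replicate 1 or 0 mg/L replicate 2. The 52 cell cycle genes had a median of -1.59 and 0 passed (adjusted p = 0.83 with an estimated correlation), beside an oocyte score of 1.32 (SD 2.12, n = 4) against 3.75 (SD 0.31, n = 2) at 0 mg/L. By limma 237 probes were higher and 33 lower. The fit with slide as a block called 69 (64 higher and 5 lower), that with all 4 samples at 0 mg/L as 1 group 2136 (1712 and 424), that with the oocyte score 160 (113 and 47) and that without the 2 dimmest arrays 83, all higher. Without UV-treated 0 mg/L replicate 1 or 2 the count was 72, all higher, or 614. It was 132, 133 or 127 without UV-treated 30.2 mg/L replicate 1, 2 or 3.

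At 58.2 mg/L of UV-treated material the largest rises, among those not given as a bound, were those of the adult globin genes hbba2 and hbaa2. The mean change of 4 adult globin genes was 3.58 with an SD of 3.82 over genes, so they did not all rise alike. The gene hbba2 rose by log2 7.14 ± 1.08 (n = 4 against 2, adjusted p = 0.000558) and hbaa2 by 6.63 ± 1.11 (adjusted p = 0.00149). The erythroid genes slc4a1a (4.64 ± 0.43, adjusted p = 1.64e-06) and alas2 (3.89 ± 0.39, adjusted p = 2.83e-06) also rose. Among stress genes, hspa1b was at least 30.3-fold higher (adjusted p = 0.000171), hsp70 rose by 4.73 ± 0.48 and hmox1a by 3.63 ± 0.72 (adjusted p = 0.00587). Among metabolising enzymes, cyp2k6 was at least 23.2-fold higher, gsta.2 rose by 4.58 ± 0.85, and cyp1a by 2.89 ± 0.43. The falls included krt1-19e (-7.17 ± 0.67, adjusted p = 1.64e-06), nos2a (-4.60 ± 0.90), nr0b2a (-3.65 ± 0.64), chia.3 (-3.62 ± 0.80) and opn1mw1 (-3.56 ± 0.64), and the galectin gene lgals9l4 was at least 19.3-fold lower. The signal of nos2a was not well above background in UV-treated 58.2 mg/L replicates 2, 3 and 4, so the size of its fall is uncertain. The liver genes gc (-3.05 ± 0.43) and pklr (-2.77 ± 0.37), for pyruvate kinase, fell too. Of 53 liver genes 4 rose and 5 fell (5 and 8 when adjusted over the list alone, adjusted p = 0.823 with an estimated correlation). Without UV-treated 0 mg/L replicate 2 the calls of hmox1a (3.14, adjusted p = 0.0662), nos2a (-3.47, adjusted p = 0.0911) and chia.3 (-3.45, adjusted p = 0.0706) ended, and without replicate 1 those of chia.3 (-3.78, adjusted p = 0.103), opn1mw1 (-3.35, adjusted p = 0.0623) and lgals9l4 (adjusted p = 0.128).

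Of 33 erythroid genes 13 rose and 0 fell at 58.2 mg/L of UV-treated material, and 16 rose and 1 fell when adjusted over the list alone. The median was 1.4 (adjusted p = 0.000918 with an estimated correlation), 1.28 with slide as a block and 1.27 within the shared slide. Of 35 heat shock genes 13 rose and 0 fell, 15 rose when adjusted over the list alone, and the median was 0.71 (adjusted p = 0.00103 with an estimated correlation), 0.67 with slide as a block. Of 33 endoplasmic reticulum stress genes 3 rose, the transcription factor atf3 (2.66 ± 0.44), the amino acid gene asns (1.51 ± 0.37) and the chaperone calr3b (1.29 ± 0.27), and 4 rose when adjusted over the list alone (adjusted p = 0.0313 with an estimated correlation). Of 42 antioxidant genes 11 rose and 0 fell, with txnb (2.39 ± 0.46) and me1 (2.22 ± 0.41), 18 rose and 2 fell when adjusted over the list alone, and the list's call was lost (adjusted p = 0.118 with an estimated correlation). Sterol synthesis genes showed 5 rises of 26, with acat2 (2.52 ± 0.27) and hmgcra (2.45 ± 0.51), and 9 when adjusted over the list alone (adjusted p = 0.118 with an estimated correlation). The call of hmgcra was lost with slide as a block (2.32, adjusted p = 0.0578) and without UV-treated 0 mg/L replicate 1 (2.00, adjusted p = 0.191). Calls that ended without that sample were also those of asns (1.27, adjusted p = 0.286), calr3b (1.35, adjusted p = 0.0789), epyc (-1.69, adjusted p = 0.165) and col2a1a (-1.40, adjusted p = 0.378). Without replicate 2 at 0 mg/L calr3b (1.23, adjusted p = 0.0569) and txnb (2.01, adjusted p = 0.0655) lost theirs, and asns and col2a1a without UV-treated 58.2 mg/L replicate 1 or 4. Of 47 collagen, cartilage and bone genes 0 rose and 5 fell, with the cartilage genes epyc (-2.18 ± 0.42) and col2a1a (-1.84 ± 0.47), and 1 rose and 13 fell when adjusted over the list alone (adjusted p = 0.606 with an estimated correlation). The muscle list had a median of -0.31, 1 of its 72 members rose and 0 fell (adjusted p = 0.756 with an estimated correlation), and its direction flipped under quantile normalization (0.00014).

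Of the genes given at 58.2 mg/L whether they passed or not, prdx1 (1.6 ± 0.38, adjusted p = 0.019), gclm (1.13 ± 0.30, adjusted p = 0.0352), gstp1.2 (1.07 ± 0.28, adjusted p = 0.0342), cyp1a, hmox1a and hsp70l (3.26 ± 0.53, adjusted p = 0.00107) rose in UV-treated material. The call of gclm ended in each of the 6 fits that left out 1 array, that of prdx1 without UV-treated 0 mg/L replicate 2 (1.17, adjusted p = 0.19) or 58.2 mg/L replicate 1, and that of gstp1.2 without UV-treated 0 mg/L replicate 1 (0.66, adjusted p = 0.511) or 58.2 mg/L replicate 1, 2 or 4. The other 12 did not pass: vtg1 was at least 4.62-fold higher (adjusted p = 0.117), hbae1.1 was at 2.76, nqo1 at 1.49, txnrd3 at 0.93, gclc at 0.77, fkbp5 at 0.48, srxn1 at 0.22, mdm2 at 0.15, pck1 at 0.10, sod1 at -0.41, cat at -0.54 and mt2 at -0.80. By limma 935 probes were higher and 496 lower. With slide as a block 532 were called (334 higher and 198 lower), 503 of them shared with the 1431. The fit with all 4 samples at 0 mg/L as 1 group gave 3588 (2239 and 1349), and that without the 2 dimmest arrays 384 (291 and 93). The count was 305 without UV-treated 0 mg/L replicate 1 and 657 without UV-treated 58.2 mg/L replicate 1. The oocyte score of these samples was 2.89 (SD 0.57, n = 4). With the score as a covariate limma called 2024 probes (1103 higher and 921 lower), beside 2390 for parent 58.2 mg/L in the same fit.

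**Figure D2:**
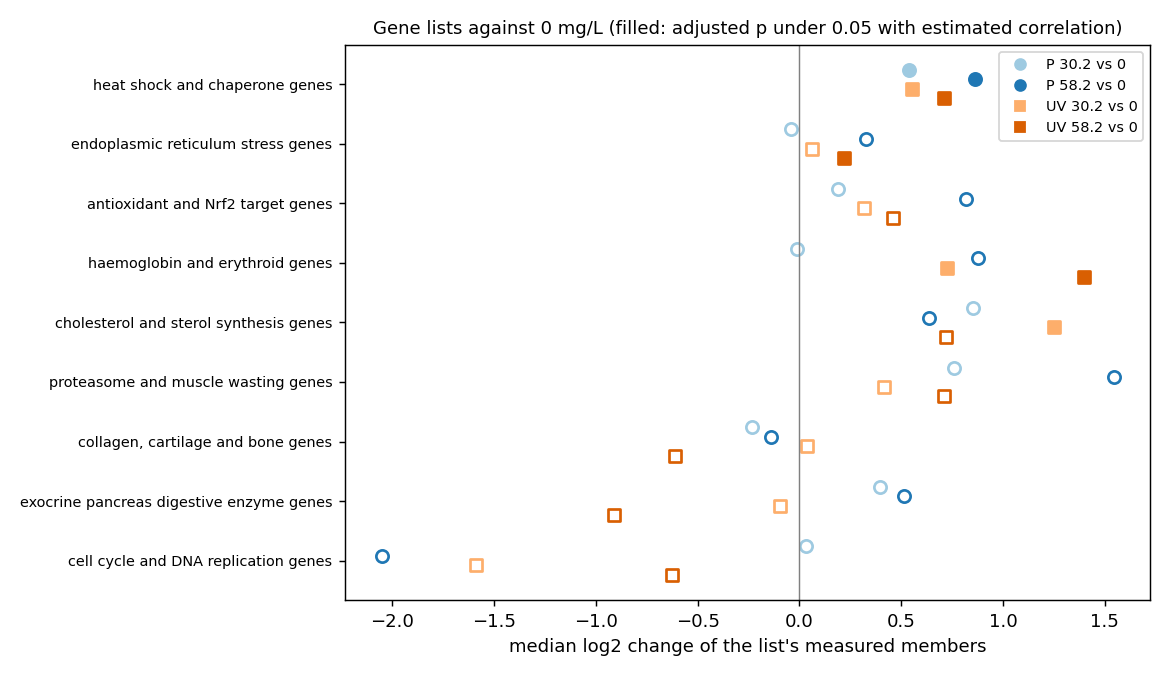
Median log2 change of the measured members of 9 gene lists (vertical axis) against 0 mg/L, with 1 symbol for each of parent and UV-treated material at 30.2 and 58.2 mg/L (horizontal axis, log2), filled where the adjusted p with an estimated correlation was under 0.05. The erythroid list stood at 0.88 in parent and 1.4 in UV-treated material at 58.2 mg/L.

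The comparison of 58.2 with 3.8 mg/L within each form set 4 arrays against 4 and used no 0 mg/L sample. The 2 parent groups met on slide 1 alone, with 1 array of each. The other 3 parent arrays at 3.8 mg/L lay on slide 3, which held no parent 58.2 mg/L array. Concentration and slide were thus partly confounded in parent material. In parent material krt1-19e fell by 7.47 ± 0.55 on the log2 scale (adjusted p = 2.3e-08), while hbba2 (6.39 ± 0.89), hspa1b (5.55 ± 0.58), hsp70 (5.46 ± 0.39) and hmox1a (4.71 ± 0.59, adjusted p = 2.49e-05) rose. The genes cyp2k6 and lepb were at least 28.6-fold and 16.5-fold higher. The immune genes nos2a (-5.35 ± 0.73) and ccl19a.2 (-4.51 ± 0.69, a chemokine) fell, and crp6, of the C-reactive protein family, fell by 3.95 ± 0.57. Of 49 innate immune genes 13 rose and 1 fell (15 and 2 when adjusted over the list alone, adjusted p = 0.451 with an estimated correlation). In UV-treated material hspa1b (5.63 ± 0.58), hbba2 (5.24 ± 0.89), gsta.2 (5.07 ± 0.69), hsp70 (4.95 ± 0.39) and ankrd1b (4.11 ± 0.49) rose, and krt1-19e (-6.82 ± 0.55, adjusted p = 1.39e-07), nos2a (-5.97 ± 0.73), opn1mw1 (-4.33 ± 0.52), mfap4.4 (-4.26 ± 0.57) and adh8a (-3.96 ± 0.44, an alcohol dehydrogenase) fell. The T cell gene cd8a was at least 29.9-fold lower (adjusted p = 0.000291). The signal of nos2a was not well above background in parent 58.2 mg/L replicates 2 and 4. Nor was it in UV-treated 58.2 mg/L replicates 2, 3 and 4, so the sizes of its falls are uncertain. Each gene named so far in this paragraph was called in all 8 fits that left out 1 array. Blocked by slide, krt1-19e was at -7.62 in parent and -6.70 in UV-treated material, and within slides that held both groups, often 1 array of each, it was at -9.16 in parent and between -7.17 and -5.90 in UV-treated material. In parent material hbbe1.1, a larval globin gene, fell (-2.94 ± 0.92, adjusted p = 0.0462) and kept its call in 0 of 8 such fits.

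Heat shock genes rose in both forms between 3.8 and 58.2 mg/L, 17 of 35 in parent material (median 0.88, adjusted p = 0.000746 with an estimated correlation) and 16 of 35 in UV-treated material, where 1 fell (median 0.84, adjusted p = 0.000508 with an estimated correlation). The counts adjusted over the list alone were 19 that rose and 1 that fell in parent and 17 that rose and 1 that fell in UV-treated material. Blocked by slide, the medians were 1.00 and 0.77. Endoplasmic reticulum stress genes rose in 8 of 33 (parent, median 0.61) and 7 of 33 (UV-treated, median 0.44), with adjusted p = 0.000746 and 0.000508 with an estimated correlation. In those lists 9 and 8 rose when adjusted over the list alone. Examples are atf3 (2.51 ± 0.36 in parent and 2.74 ± 0.36 in UV-treated material), calr3b (1.64 ± 0.22 and 1.68 ± 0.22) and dnajb9b (1.39 ± 0.35 and 1.69 ± 0.35), whose call in parent material ended without parent 58.2 mg/L replicate 1 (1.25, adjusted p = 0.0553). Of 33 erythroid genes 13 rose and 0 fell in UV-treated material, with hmbsb (3.1 ± 0.26), a haem synthesis gene, and slc4a1a (3.59 ± 0.35). Their median was 1.26 (adjusted p = 0.00133 with an estimated correlation), 1.34 with slide as a block. There were 18 that rose and 1 that fell when adjusted over the list alone. In parent material 11 rose and 1 fell, 14 rose and 2 fell when adjusted over the list alone, and the list's call was lost (adjusted p = 0.106 with an estimated correlation). Proteasome and muscle wasting genes rose in 29 of 46 (parent, adjusted p = 0.112 with an estimated correlation) and 32 of 46 (UV-treated, adjusted p = 0.0513 with an estimated correlation), 39 and 37 when adjusted over the list alone. Lysosome genes rose in 6 of 34 in UV-treated material (median 0.50, adjusted p = 0.0183 with an estimated correlation; 6 when adjusted over the list alone), with ctslb at 2.05 ± 0.28.

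In UV-treated material, 22 of 47 collagen, cartilage and bone genes fell and 0 rose between 3.8 and 58.2 mg/L, with col1a1a (-2.62 ± 0.46), col10a1a (-2.73 ± 0.69) and the tendon gene tnmd (-3.34 ± 0.90). The count adjusted over the list alone was 28, with a median of -1.02 (adjusted p = 0.135 with an estimated correlation), -1.12 with slide as a block. Of 47 photoreceptor genes 12 fell, with the cone kinase gene grk7a (-1.50 ± 0.26) and the UV opsin opn1sw1 (-1.61 ± 0.31), and 17 fell when adjusted over the list alone (adjusted p = 0.333 with an estimated correlation). Of 33 digestive enzyme genes 10 fell, with cpa1 (-2.45 ± 0.69) and ela2l (-1.82 ± 0.43), and 1 rose and 19 fell when adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). Of 53 liver genes 4 rose and 10 fell, with gc (-3.67 ± 0.35), nr0b2a (-3.87 ± 0.53) and fabp10a (-3.02 ± 0.45), and 4 rose and 16 fell when adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). In parent material 12 of 47 collagen, cartilage and bone genes fell and 3 rose, with col2a1a (-1.86 ± 0.39) and col9a3 (-1.68 ± 0.32), and 5 rose and 16 fell when adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). The calls of tnmd and cpa1 each ended in 4 of the 8 fits that left out 1 array, at -2.58 (adjusted p = 0.0966) without UV-treated 58.2 mg/L replicate 4 and -2.01 (adjusted p = 0.116) without UV-treated 3.8 mg/L replicate 1. That of col10a1a ended without UV-treated 58.2 or 3.8 mg/L replicate 2 (-2.15 and -2.11), and that of ela2l without UV-treated 58.2 mg/L replicate 1 (-1.51, adjusted p = 0.051). In all, 2286 probes were higher and 1072 lower in parent material, and 1414 were higher and 1542 lower in UV-treated material. More were higher than lower in UV-treated material with quantile normalization (1720 and 1426), normexp and quantile normalization (1647 and 1249), the oocyte score as a covariate (1794 and 1456), the oocyte score and slide (1439 and 1224) and without the 2 dimmest arrays (1203 and 868). With slide as a block 1587 and 2286 were called, 1522 and 2192 of them shared with the fit without it. The parent count was 2058 without parent 3.8 mg/L replicate 2 and 1847 without parent 58.2 mg/L replicate 1. The UV-treated count was 1843 (1003 higher) or 1965 (1130 higher) without UV-treated 3.8 mg/L replicate 1 or 2 and 1667 without UV-treated 58.2 mg/L replicate 1.

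Between the forms at the same concentration few probes differed. At 3.8 mg/L the red cone opsin genes opn1lw1 (log2 2.75 ± 0.39, n = 4 against 4, adjusted p = 0.00949, chromosome 11, 26413429 to 26413488) and opn1lw2 (2.52 ± 0.43, adjusted p = 0.0398) were higher in UV-treated samples, as was aanat2, which makes the precursor of melatonin (1.84 ± 0.29, adjusted p = 0.0167, chromosome 3, 55744880 to 55744939), and the apoptosis inhibitor gene xiap was lower (-1.11 ± 0.17, adjusted p = 0.0167). The other 4 probes were chosen after their values were seen, and measured the clock genes per1a (-1.99 ± 0.35, adjusted p = 0.0409) and ciarta (-1.39 ± 0.25, adjusted p = 0.0453) and 2 sequences without a gene symbol (1.49 and -1.91). Blocked by slide limma called 0 probes, opn1lw1 being at 2.73 (adjusted p = 0.139), and within the slides that held both groups opn1lw1 was at 3.36 and 2.21. Leaving out 1 array gave 1 to 6 probes. The count was 4, 1 or 1 without parent 3.8 mg/L replicate 1, 2 or 4 and 4, 2, 2 or 1 without UV-treated 3.8 mg/L replicate 1, 2, 3 or 4. The gene opn1lw1 was called in all 8 of these fits, aanat2 and xiap in 3 and opn1lw2 in 0. Of 47 photoreceptor genes 2 rose, 5 when adjusted over the list alone (adjusted p = 0.907 with an estimated correlation).

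At 30.2 mg/L limma called 2 probes, both higher in UV-treated samples and without a gene symbol (4.76 ± 0.59, adjusted p = 0.00113, and 1.54 ± 0.25, adjusted p = 0.0393), beside 7724 at an unadjusted p under 0.05. The genes of smallest p did not pass and included klf1 (2.03 ± 0.38, adjusted p = 0.137), opn1mw3 (1.25 ± 0.24, adjusted p = 0.158) and chmp4c (-1.41 ± 0.24, adjusted p = 0.0607). The median shift of all tested probes was 0.19 here and -0.19 at 58.2 mg/L. At 58.2 mg/L limma called 1 probe higher, for the interferon-inducible gene ifi27.4 (2.2 ± 0.34, adjusted p = 0.0406), a probe chosen after its value was seen, and 1 lower, for the ribosomal protein gene rps27.2 (-1.28 ± 0.20, adjusted p = 0.0406), beside 4470 at an unadjusted p under 0.05. The brightest probe of ifi27.4 was at 1.76 (adjusted p = 0.366). Blocked by slide the limma count at 58.2 mg/L was 0. Without 1 array it ranged from 0 to 3 at 58.2 mg/L and from 1 to 4 at 30.2 mg/L. It was 0 at 58.2 mg/L without parent 58.2 mg/L replicate 1, 2 or 3 or UV-treated replicate 2 or 4, and 1 without UV-treated replicate 1 or 3. At 30.2 mg/L it was 4 without parent 30.2 mg/L replicate 1, and 1 without parent replicate 2, 3 or 4 or UV-treated replicate 1, 3 or 4. None of the 18 measured genes of the fixed set passed at 58.2 mg/L, where hmox1a differed by -1.14 (adjusted p = 0.432), hsp70l by -1.01 (adjusted p = 0.388), cyp1a by 0.16 (adjusted p = 0.848) and hbae1.1 by 3.56 (adjusted p = 0.367). The others were mt2 at 1.11, nqo1 at 0.86, gstp1.2 at 0.69, vtg1 at 0.54, gclc at 0.40, txnrd3 at 0.33, gclm at 0.29, sod1 at 0.24, cat at 0.18, prdx1 at 0.11, mdm2 at -0.01, srxn1 at -0.19, fkbp5 at -0.25 and pck1 at -0.49. The cell cycle list was higher in UV-treated than parent samples at 58.2 mg/L with 21 members past 0.05 adjusted over the list alone, 0 over all probes, a median of 1.43 and adjusted p = 0.326 with an estimated correlation, beside oocyte scores of 2.89 and -0.11. At 30.2 mg/L, 39 members were lower adjusted over the list alone and 0 over all probes (median -1.63, adjusted p = 0.852 with an estimated correlation), beside oocyte scores of 1.32 and 3.76. The erythroid list at 58.2 mg/L had 9 members higher adjusted over the list alone and 0 over all probes (median 0.47, adjusted p = 0.0517 with an estimated correlation).

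The interaction of form and concentration gave 0 probes by limma, with 5494 (14.7%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.236. Without UV-treated 0 mg/L replicate 1 or 2 the count was 7 or 25, and without parent 0 mg/L replicate 1 or 2 it was 1 or 5. Of 114 camera tests of gene lists for the interaction, 47 were below 0.05 with the preset correlation. With an estimated correlation 0 were, and the smallest adjusted p was 0.197. The 95% interval of the difference between forms lay within 2-fold for 49.2% of probes at 58.2 mg/L, 42.4% at 30.2 mg/L and 60% at 3.8 mg/L. For 58.2 against 3.8 mg/L the forms shared 1012 probes that were higher and 644 that were lower, where independent lists would share 86.6 and 44.3. Of the probes called in both forms 0 went opposite ways, and of 4658 called in either form 4543 had the same sign in both. These comparisons have no array in common. Across probes, which are not independent replicates, the log2 changes of the forms correlated with r = 0.51 there, 0.55 for 58.2 against 0 mg/L and 0.18 for 30.2 against 0 mg/L. Against 0 mg/L at 58.2 mg/L they shared 636 higher and 214 lower probes (81.7 and 18.8 for independent lists), and 1 probe called in both forms went opposite ways. Of 5252 probes called there in either form 4896 had the same sign in both. Of 226 and 270 probes called at 30.2 mg/L against 0 mg/L they shared 39 higher and 2 lower (0.934 and 0.0699 for independent lists).

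The average difference between forms over the 3 concentrations, a comparison of 12 arrays with 12 added after the data were seen, gave 20 probes higher and 3 lower in UV-treated samples. These included opn1lw1 (2.21 ± 0.22, adjusted p = 2.69e-05), opn1lw2 (1.83 ± 0.25), opn1mw2 (1.44 ± 0.24), aanat2 (1.11 ± 0.17) and the interferon-stimulated gene isg15 (2.21 ± 0.41, adjusted p = 0.0322), and klf1 (1.21 ± 0.22) and alas2 (0.95 ± 0.18, adjusted p = 0.0425) from the erythroid list. All were chosen after their values were seen.

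**Figure D3:**
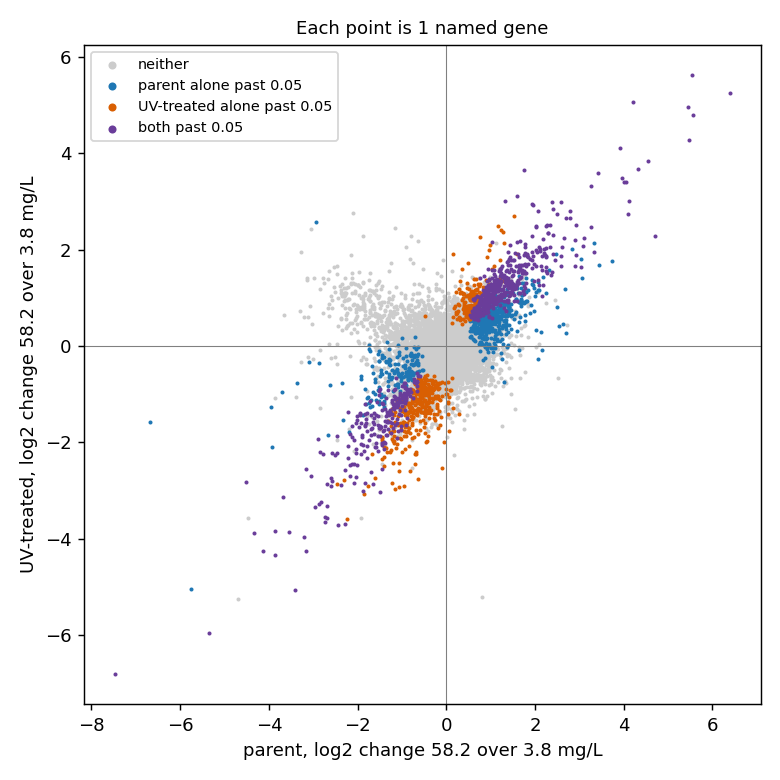
Log2 change of each named gene (1 point per gene) for 58.2 against 3.8 mg/L, parent material on the horizontal and UV-treated material on the vertical axis, coloured by which comparison passed 0.05. The gene krt1-19e lies at -7.47 in parent and -6.82 in UV-treated material.

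The oocyte score differed within and between groups. Its mean was 1.98 (SD 1.96) at parent 3.8 mg/L and 1.88 (SD 2.67) at UV-treated 3.8 mg/L, and 3.76 (SD 0.11) at parent 30.2 mg/L, with n = 4 in each. In two-sided exact permutation tests over 5 comparisons, parent 58.2 against 30.2 mg/L differed by -3.87 (p = 0.0286, the smallest that 4 against 4 allow, adjusted p = 0.0477) and parent 58.2 against 3.8 mg/L by -2.08 (p = 0.171, adjusted p = 0.214). UV-treated against parent material differed by 2.99 at 58.2 mg/L and by -2.44 at 30.2 mg/L (exact p = 0.0286 and adjusted p = 0.0477 for each), and UV-treated 58.2 against 3.8 mg/L by 1.01 (exact p = 0.629).

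**Figure D4:**
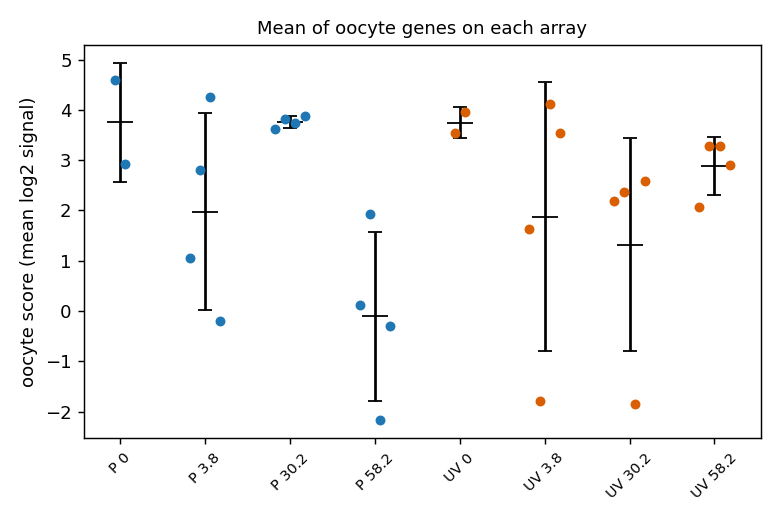
Mean log2 signal of 33 oocyte genes (vertical axis), 1 point per array, by group (horizontal axis, P for parent and UV for UV-treated material, mg/L), with the group mean and SD. Parent 58.2 mg/L averages -0.11, and parent 30.2 mg/L averages 3.76.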

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

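The average between forms over 3 concentrations and the tests of ovary content, array brightness, exposure, clock, eye tissue and red blood cells were chosen after the results were seen. Slide as a block and other splits were chosen before. The test of slide for the cone opsins used that average, so it was not fixed before.

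Of 78 groups of 4 arrays, over array measures, the oocyte score and 10 genes, 4 held an array far from the other 3, and chance gives about 1 in 20. The oocyte score was -1.85 in UV-treated 30.2 mg/L replicate 3, where the others lay from 2.18 to 2.58. The log2 value of hsp70l was 1.98 in parent 30.2 mg/L replicate 3, where the others lay from 2.82 to 2.93. In the same array opn1lw1 was at -0.23, where the others lay from -1.0 to -0.90. In UV-treated 58.2 mg/L replicate 3 opn1lw1 was at -0.60, where the others lay from 1.4 to 1.47.

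The cell cycle genes that fell at parent 58.2 mg/L went with the oocyte score, with which their list mean correlated within groups over 28 arrays (Pearson r = 0.92 and Spearman rho = 0.97, each with permutation p = 1e-05, the smallest these permutations can give, and 3e-05 adjusted over 3 relations; r = 0.93 without the 2 arrays farthest from the median). Pools of 4 fish that differed in ovary content are a candidate explanation: with the score as a covariate 1 of the 20 members stayed called, their median moved from -2.96 to -0.61 and their median SE from 0.94 to 0.45, so the calls ended because the change shrank. Of the 33 score genes 0 are in the cell cycle list and 6 are in the vitellogenin list, and the score was chosen after the data were seen, so this test cannot say why the score differs between pools. Array brightness stays open (Pearson r within groups 0.46, permutation p = 0.0943, Spearman rho = 0.36, permutation p = 0.113, the same when adjusted, and r = 0.24 without 2 arrays), and the anti-Mullerian hormone gene amh went against the score (r = -0.54, adjusted permutation p = 0.0322, rho = -0.54, adjusted permutation p = 0.0219, r = -0.43 without 2 arrays). Exposure stays open too, since parent 58.2 against 3.8 mg/L gave exact p = 0.171 for the score with a difference of -2.08, while 58.2 against 30.2 mg/L gave -3.87 (exact p = 0.0286, the smallest possible, and 0.0477 adjusted over 5 comparisons).

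The cone opsins opn1lw1, opn1lw2, opn1mw2 and opn1mw3 and aanat2 passed, higher in UV-treated samples, in the average over 3 concentrations, while at single concentrations the opsins opn1lw1 and opn1lw2 and aanat2 passed at 3.8 mg/L alone, none of them with slide as a block, and the photoreceptor list had adjusted p = 0.614 with an estimated correlation in that average. More eye tissue is argued against by the other 39 photoreceptor genes, whose median difference was 0.15 (SD 0.28), and by 51 lens crystallins at 0.02. Slide is argued against by opn1lw1, which was at 2.21 in that average with and without it as a block, though the average was chosen after the data were seen. Another phase of the daily clock at sampling may explain the pattern: 12 morning minus 8 evening clock genes differed by -0.60 (permutation p = 0.00014, 100000 resamples), but these arms were chosen after clock genes were seen to move. At 0 mg/L, outside this test, the mean of the clock genes was higher in UV-treated (1.61, SD 1.14) than in parent samples (0.94, SD 0.035, n = 2 in each). There opn1lw1 was at -0.54 and -0.55 in UV-treated samples, between the parent values of -0.96 and -0.0072. The difference of this gene was thus not seen between the sets at 0 mg/L. Time of sampling was not analysed here, and the form of the material stays open as an untested biological explanation.

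Of 33 erythroid genes 13 rose and 0 fell between 3.8 and 58.2 mg/L of UV-treated material (adjusted p = 0.00133 with an estimated correlation), and 11 rose and 1 fell in parent material, where the list's call was lost (adjusted p = 0.106 with an estimated correlation). In parent material more red blood cells stay open, since 5 larval globins had a mean change of -1.86 (SE 0.74, over genes) from 3.8 mg/L but of 0.65 (SE 0.14) from 0 mg/L. The means of 4 adult globins were 3.03 (SD 3.42, over genes) and 2.41 (SD 3.04), so these 4 did not change alike. In UV-treated material the larval mean was 1.2 (SE 0.80), close to 1.18, which is 50% of the adult mean (2.36, SD 3.08 over genes). More red blood cells stay open there too. The margin of 1 SE and the comparison with 0 mg/L were added after these values were seen. Slide is argued against by the list median in UV-treated material, which was 1.34 with it as a block and 1.26 without. A change of expression within red blood cells could remain as an explanation, and was not tested.

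Other splits of the same 8 arrays into 4 and 4 were counted, 35 for each comparison, the real one included. For parent 58.2 against 3.8 mg/L 1 split, the real one, gave as many probes (3358, highest other 0), and for UV-treated material likewise 1 (2956, highest other 95). Between forms at 30.2 mg/L it was 1 too (2 probes, highest other 0). That count rests on 2 probes and was 1 in 6 of the 8 fits that left out 1 array. There limma called 0 probes with probes above background on all arrays (5907 unadjusted) and with the oocyte score and slide (1516 unadjusted). The share of 1 in 35, the smallest possible, is 0.0286 in each of these 3 comparisons, and 0.0476 by the Benjamini-Hochberg or 0.143 by the Bonferroni adjustment over 5. The real split stood apart for 58.2 against 3.8 mg/L in both forms. By Bonferroni no share could fall under 0.05, so the splits alone do not exclude chance, and they took no account of slide. Between forms at 58.2 mg/L 2 splits gave 2 probes (highest other 2), and at 3.8 mg/L 5 splits gave at least the real 8, so chance cannot be excluded there either. The highest other count at 3.8 mg/L, 4515, points to a structure of the samples or arrays. It set UV-treated replicates 1 and 2 and parent replicates 1 and 4 against the rest. This puts slides 1, 2, 1 and 3 against 3, 4, 3 and 3, so slide 3 is on both sides. The scanning runs of these arrays, numbered in time order, were 3, 2, 3 and 1 against 6, 4, 6 and 6. No run is on both sides, so scanning run and the samples cannot be told apart in this split. Scanning run was not tested as a block. The oocyte score ran from -1.79 to 1.63 in the first 4 arrays and from 2.80 to 4.25 in the others, and the first principal component from -122.1 to -48.1 and from 4.45 to 124.8. With slide as a block the comparison of forms there gave 0 probes by limma (983 unadjusted).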

How the results depend on the processing

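The oocyte covariate, alone or with slide, and the fit without the 2 dimmest arrays were chosen after seeing the data. Counts below are probes called by limma, after the counts of the report, and the cause of each change was not tested, except that 1 probe per gene tests fewer probes. The authors' value table gave all 12 counts within 1.5 times. Of 733 results for named genes, 567 kept their side of the threshold with slide as a block and 166 lost the call. With quantile normalization these were 699 and 28 (6 gained it). With normexp and quantile normalization they were 647 and 79 (7 gained it), and with the oocyte score 647 and 83 (3 gained it). No named gene that passed the threshold in either fit changed direction under these settings, the replicate block or all 4 samples at 0 mg/L as 1 group. Results that passed in neither fit were not compared for direction. Of 418 list results 256 kept their side of the threshold with an estimated correlation and 162 lost their call. Signal over background limited the measurement in that 63.4% to 81.5% of spots were well above it.

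For parent 3.8 mg/L against 0 mg/L the count was 2 with quantile normalization, 0 with normexp and quantile normalization (3170 unadjusted), 1 with no filter on dim probes, 0 with probes above background on all arrays (2266 unadjusted), 0 with slide as a block (2868 unadjusted), 1 with 1 probe per gene, 2 with trend and robust variance, 0 with all 4 samples at 0 mg/L as 1 group (3276 unadjusted), 1 with the oocyte score and 0 with the oocyte score and slide (2395 unadjusted). For parent 30.2 mg/L it was 60 with slide as a block, 120 with 1 probe per gene, 504 with the oocyte score and 415 without the 2 dimmest arrays. For parent 58.2 mg/L it was 3048 with slide as a block, 2574 with 1 probe per gene, 7838 with all 4 samples at 0 mg/L as 1 group, 2390 with the oocyte score and 1847 with the oocyte score and slide.

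For UV-treated 3.8 mg/L it was 4 with all 4 samples at 0 mg/L as 1 group and 16 without the 2 dimmest arrays. For UV-treated 30.2 mg/L it was 168 with probes above background on all arrays, 69 with slide as a block, 115 with 1 probe per gene, 2136 with all 4 samples at 0 mg/L as 1 group, 160 with the oocyte score, 49 with the oocyte score and slide and 83 without the 2 dimmest arrays. For UV-treated 58.2 mg/L it was 532 with slide as a block, 827 with 1 probe per gene, 3588 with all 4 samples at 0 mg/L as 1 group and 384 without the 2 dimmest arrays. The interaction gave 25 with all 4 samples at 0 mg/L as 1 group and 7 without the 2 dimmest arrays. For 58.2 against 3.8 mg/L parent material gave 1587 with slide as a block, 1954 with 1 probe per gene and 1966 with the oocyte score and slide, and UV-treated material gave 1826 with 1 probe per gene.

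Between forms at 3.8 mg/L the count was 4 with no filter on dim probes, 0 with slide as a block (983 unadjusted), 14 with the oocyte score, 1 with the oocyte score and slide and 4 without the 2 dimmest arrays. At 30.2 mg/L it was 1 with quantile normalization, 1 with normexp and quantile normalization, 1 with no filter on dim probes, 0 with probes above background on all arrays (5907 unadjusted), 1 with trend and robust variance, 1 with the oocyte score, 0 with the oocyte score and slide (1516 unadjusted) and 4 without the 2 dimmest arrays. At 58.2 mg/L it was 4 with quantile normalization, 4 with normexp and quantile normalization, 0 with no filter on dim probes (4789 unadjusted), 0 with slide as a block (3389 unadjusted), 1 with 1 probe per gene, 1 with the oocyte score and 0 with the oocyte score and slide (1598 unadjusted).

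The replicate block gave 0 probes for parent 3.8 mg/L against 0 mg/L (3197 unadjusted), 145 for parent 30.2 mg/L, 5 between forms at 3.8 mg/L, 0 between forms at 58.2 mg/L (4714 unadjusted) and 2 for the interaction. Under the replicate block 674 gene results kept their side of the threshold, 56 lost their call and 3 gained one. The numbers do not pair the samples: deviations of 86 pairs of arrays with the same replicate number correlated between -0.53 and 0.69 (median 0.01), with 36 over 0.1.

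Without 1 array in turn, the counts ranged from 1 to 123 for parent 3.8 mg/L against 0 mg/L, from 52 to 318 for 30.2 mg/L and from 742 to 7866 for 58.2 mg/L. For UV-treated material they ranged from 0 to 169, from 72 to 614 and from 305 to 1745 in the same order of concentration. Between forms they ranged from 1 to 6, from 1 to 4 and from 0 to 3 from the lowest to the highest concentration. The interaction ranged from 0 to 25, with 1, 5, 7 and 25 without parent 0 mg/L replicate 1 or 2 or UV-treated 0 mg/L replicate 1 or 2. For 58.2 against 3.8 mg/L they ranged from 1847 to 3100 in parent and from 1667 to 2912 in UV-treated material. A lone 0 mg/L sample was assumed to vary like the other groups.

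Changes of direction were scored only for lists past the threshold in either fit. Medians of other lists could change sign without being counted here. That of the liver list at parent 58.2 mg/L was -0.08, and 0.03 with slide as a block. Among the scored lists, medians changed direction under quantile normalization for ribosomal protein genes at parent 3.8 mg/L (0.063) and 58.2 mg/L (0.077). They also did so for these genes at UV-treated 30.2 mg/L (0.073) and 58.2 mg/L (0.028) and between forms at 3.8 mg/L (-0.041). The same held for 58.2 against 3.8 mg/L in parent (0.070) and UV-treated material (0.017). Medians also changed direction under quantile normalization for mitochondrial respiratory chain genes at parent 58.2 mg/L against 0 mg/L (0.089) and 3.8 mg/L (0.13). So did those of lens crystallin genes at parent 30.2 mg/L (0.13) and muscle genes at UV-treated 58.2 mg/L (0.00014). With all 4 samples at 0 mg/L as 1 group the proteasome list at UV-treated 3.8 mg/L did (0.060). With the oocyte score as covariate the mitochondrial list did between forms at 30.2 mg/L (0.017), and at 58.2 mg/L between forms the fatty acid (0.091), ribosomal (0.12), photoreceptor (0.14), muscle (0.15), heart (0.21) and skin (0.13) lists did, as did the cell cycle list for parent 58.2 against 3.8 mg/L (0.012).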

Other observations

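No test in this part was chosen after its result was seen. Between 3.8 and 58.2 mg/L of parent material 9 of 26 sterol synthesis genes rose and 0 fell, with cyp51 (log2 3.07 ± 0.64, SE, n = 4 against 4) and acat2 (2.29 ± 0.22), and 13 rose when adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). Of 35 p53 and DNA damage genes 7 rose, among them the growth arrest genes gadd45aa (1.65 ± 0.27) and gadd45bb (1.47 ± 0.29), and 8 rose when adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Of 49 innate immune genes 13 rose and 1, nos2a, fell, and the collagenase gene mmp13a (4.12 ± 0.59) and the acute phase gene saa (3.34 ± 0.79) were among the rises. Adjusted over the list alone 15 rose and 2 fell (adjusted p = 0.451 with an estimated correlation). The genes named here were called in all 8 fits that left out 1 array.

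In UV-treated material 5 of 20 iron and metal genes rose and 0 fell at 58.2 mg/L against 0 mg/L, with the iron exporter slc40a1 (log2 2.19 ± 0.39, SE, n = 4 against 2, adjusted p = 0.00259 by limma), the importer slc11a2 (1.29 ± 0.24) and the transferrin receptor tfr1a (at least 5.61-fold), each called in all 6 fits that left out 1 array. Adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.216 with an estimated correlation). Between 3.8 and 58.2 mg/L 11 of 72 muscle contractile genes fell, with the calcium store gene casq1a at -3.06 ± 0.70, and 1 rose and 30 fell when adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). Of 51 lens crystallins 3 fell, with cryaba (-2.13 ± 0.46), and 8 fell when adjusted over the list alone (adjusted p = 0.272 with an estimated correlation).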
